A study of Mus musculus and Homo sapiens with 37 samples.

How the data were processed

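The samples were libraries of RNA from a mouse glioma model and from human patient-derived orthotopic xenografts (PDOX, tumor tissue of a patient grown in the brain of a mouse). Per the labels, the mouse tumors were made by in utero electroporation of CRISPR constructs into CD-1 embryos and were collected at postnatal day 65 or 80. Tumors were dissociated with papain. Endothelial cells were sorted by flow cytometry with antibodies against CD31 (Pecam1), podoplanin (Pdpn) and Vegfr3 (Flt4), per the labels' protocols. The labels name the sorted fractions TAV, TDEC, TDBEC and TDLEC. The last 3 are tumor-derived endothelial cells and, among these, blood and lymphatic endothelial cells; TAV is not spelled out, and the gate that parts TAV from TDEC is not given in the sources used here.

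Bulk tumor, TAV and TDEC libraries were made with the NuGEN Trio kit and TDBEC and TDLEC libraries, mouse and human, with the SMART-Seq ultra low input kit, per the labels' protocols. Libraries of different kits were not compared. Single cells of 1 bulk tumor library and 1 library enriched for CD31 with magnetic beads were made with droplet chemistry, counted with Cell Ranger against mm10 and exported from Seurat, per the labels' protocols.

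For the sorted and bulk libraries the authors deposited estimated counts per transcript, with transcript lengths, in the layout Salmon writes, per the file headers. The TPM values that the authors' Salmon runs gave beside them, per the file headers, were used only to weight transcript lengths for the transcript-length offset. The submitters' processing notes name Salmon 1.1.0, FastQC 0.10.1, MultiQC 0.9, DESeq2 1.20.0 and the builds mm10 and GRCh38. For the single cells the authors deposited UMI counts per gene and cell. These matrices held no gene seen in under 3 cells, so a gene absent from them was treated as not listed, not as measured at 0.

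Each mouse file held 117135 transcripts, of which 115973 matched GENCODE M21 and were summed to 35523 genes. The other transcript IDs held 0.344% to 0.985% of a mouse library's reads and were left out. Human files held 227063 transcript IDs. The tables at hand pair no human ID with a gene name, so the human libraries were tested per transcript, and human gene lists, removal of human mitochondrial genes and the planned test of the mouse genes in the human libraries were not analysed here. The plan also left XIST, TSIX and genes of the Y chromosome out of the human test. Without gene names they could not be removed and stayed in the fit. Coordinates are those of GENCODE M21 on mm10.

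Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter and the quasi-likelihood test with robust estimates, adjusted by Benjamini-Hochberg with a threshold of 0.05. The 18 bulk tumor, TAV and TDEC libraries shared 1 fit with postnatal day as an added factor, so that the cell types were compared at the same age. Age effects came from the same libraries with 1 mean per cell type and day. The 10 mouse TDBEC and TDLEC libraries and the 7 human libraries had a fit each, with no covariate. CPM values in the text were scaled by TMM over the tested genes, given as mean ± SD over libraries; plotted CPM values and those of libraries that stood apart were scaled by TMM over all genes and differ slightly. Log2 fold changes come from the fit, are given ± standard error and, for TAV and TDEC, are corrected for age, so they can differ from the ratio of the mean CPM values.

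Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. There were 32 fixed lists, of which the sort markers were not tested. Members were also counted at adjusted p under 0.05 over all genes and adjusted over the list alone. Groups, designs, alternatives, lists, cell type markers and the rule for named genes were set before the data were examined. That rule took, per comparison, the 8 largest rises and 8 largest falls among called genes with a mean of 10 CPM or more and no overlap of CPM between the groups, up to 4 members per list by smallest p, and the genes Pecam1, Pdpn, Flt4, Cdh5, Kdr, Prox1, Lyve1, Nf1 and Trp53; a further gene set beforehand is not reported here. Predicted genes and pseudogenes were passed over. Where all libraries of a group had 0 counts, a fold is given as a lower bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio of pooled counts is given with its exact 95% interval.

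The steps were tested on simulated data with the libraries' own means and depths, with 100 genes changed 4-fold and 100 changed 16-fold. At 4-fold, 20.0% were called for TAV against bulk tumor, 35.0% each for TDEC against bulk tumor and TDEC against TAV, 12.0% for TDEC at day 80 against day 65, 2.0% for bulk tumor by age and 44.0% for mouse TDLEC against TDBEC. At 16-fold, the shares were 63.0%, 70.0% and 77.0% for the first 3 comparisons, 52.0% and 28.0% for the ages and 75.0% for TDLEC. For the difference of age effects 0% and 23.0% were called, and for the human libraries 0% and 2.0%. At most 3 unchanged features were called in any comparison.

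Single cells were analysed in scanpy 1.11.5. Cells with 200 genes or more and up to 20% mitochondrial UMIs were kept. Both libraries were clustered together without batch correction, on 2000 variable genes, 30 principal components and 15 neighbors, with Leiden (igraph 0.11.9) at resolution 1. A cluster was called "X-like" from the fixed markers when at least 3 of them were 4-fold above the median cluster, its mean marker score led that of the next type by 0.5, and no other type had more markers among its top genes. Scrublet called 0 cells of the bulk tumor library and 3 of the CD31-enriched library (0.112%), so it did not work on the first and doublets remain a limit. With 1 library per group there is no test: values are given with exact 95% Poisson or binomial intervals, which cover counting error only. Ratios of CPM between libraries within endothelial-like cells were ranked over 9022 genes with 50 UMIs or more in either, and the 8 highest and 8 lowest were named. A list's median log2 ratio, with 10 CPM added, was placed among 10000 random lists of the same size matched in 20 expression bins. Shares of cells with a UMI were also taken after thinning each cell to 500 UMIs.

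Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, limma's voomWithQualityWeights, a transcript-length offset, removal of mitochondrial genes, leaving out each library, no age term, only the 2 cell types compared, day 65 or day 80 only, only that cell type for age effects, an estimated correlation for lists, and for single cells Leiden resolutions 0.5 and 2.0, doublets kept and a mitochondrial limit of 10%. Removal of Lars2, Gm20594 and Gm10800 (genes whose reads vary between Trio libraries), removal of immunoglobulin genes, leaving out TAV 5 and TDEC 5 together, and a doublet score limit of 0.25 were chosen after seeing the data.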

Results

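RNA was measured in whole mouse gliomas, in endothelial fractions sorted from them, in endothelial fractions sorted from human xenografts and in single cells of 2 mouse glioma preparations. The series' design text says that bulk and single-cell sequencing were used to look at how TAV and TDEC, both endothelial fractions of the tumor, relate to each other, and that a xenograft model was used beside the mouse model. The mouse groups were bulk tumor (n = 5; 3 libraries from postnatal day 80 and 2 from day 65), TAV (n = 5; 4 from day 65 and 1 from day 80), TDEC (n = 8; 5 from day 65 and 3 from day 80), TDBEC (n = 4) and TDLEC (n = 6). The human xenograft groups were TDBEC (n = 5) and TDLEC (n = 2). The labels do not say which libraries come from separate animals or donors, so p-values measure the spread between these samples, which may be technical in part. Intervals and lower bounds of folds cover counting error only.

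Depth differed widely between libraries. Bulk tumor libraries held 2072403 to 5471862 estimated reads, TAV libraries 1138318 to 9037188 and TDEC libraries 663449 to 15595816. The shallowest, TDEC 5, also had 34.7% of its reads on Lars2, a mitochondrial leucyl-tRNA synthetase gene. TDEC 8 had 22.5% there, and the other TDEC libraries 1.24% to 5.15%. In the mouse TDBEC and TDLEC libraries, made with the other kit, the Lars2 share was 0.042% to 0.122%. Whether the kit or library quality sets this share was not tested, so it need not reflect the level of Lars2 mRNA. Mouse TDBEC libraries held 8793803 to 13906087 reads and TDLEC libraries 8625631 to 69434466. Human TDBEC libraries held 2326035 to 10589542 and human TDLEC libraries 3713419 to 6591759. In bulk tumor, mitochondrial genes took 17.4% and 15.8% of the reads of the day 65 libraries and 4.26% to 7.74% of those of day 80.

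The labels do not name the genes edited in the tumor model. Nf1 and Trp53, tumor suppressor genes used in such models, were read in every bulk tumor, TAV and TDEC library. Nf1 stood at 108 to 191 CPM in bulk tumor, 110.4 to 266 CPM in TAV and 89.2 to 174 CPM in TDEC. Trp53 stood at 19.3 to 63.1, 42.9 to 91.7 and 38.5 to 109 CPM in the same groups. No unedited tissue was analysed here, and small edits need not change the RNA level of a gene, so these values check no label. Neither gene passed edgeR's quasi-likelihood test of TAV or TDEC against bulk tumor, where the log2 fold changes lay between −0.08 ± 0.28 for Nf1 in TDEC and 0.61 ± 0.42 for Trp53 in TAV.

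TAV libraries were compared with bulk tumor to ask which genes mark this sorted fraction. They carried the RNA of brain endothelium. Of the 25 tested pan-endothelial genes 24 rose (25 adjusted over the list alone), among them Cdh5, the endothelial cadherin on chromosome 8 (104101625 to 104144511), at 575 ± 214 CPM against 12.5 ± 11.1 CPM, a log2 fold change of 5.23 ± 0.51. Pecam1, on which the cells were sorted, stood at 582 ± 194 against 48.4 ± 15.1 CPM and is no finding. Of the 24 blood-brain barrier genes 23 rose (24 adjusted over the list alone), with the efflux pump gene Abcb1a at 951 ± 335 against 9.38 ± 5.44 CPM (6.40 ± 0.43) and the organic anion transporter gene Slco1a4 at 2141 ± 768 against 9.06 ± 5.53 CPM (7.55 ± 0.77). Of 20 arterial genes 13 rose (16 adjusted over the list alone), including Bmx, a kinase gene of arterial endothelium with no read in any bulk tumor library, which was at least 158-fold higher, and the Notch ligand gene Dll4 (5.22 ± 0.94). Vegf receptor genes rose too: of the 19 genes of the VEGF and angiopoietin list 8 rose (10 up and 1 down adjusted over the list alone), with Flt1 at 5.01 ± 0.51 and Flt4 at 3.73 ± 0.59, the latter a sort marker.

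Genes of the mural, matrix and lymphatic lists were also higher in TAV. Of 17 mural cell genes 11 rose (14 adjusted over the list alone), among them Rgs5, a pericyte marker, at 4927 ± 3430 against 105 ± 79.5 CPM (4.68 ± 0.76) and Vtn (5.35 ± 0.55). Of 24 matrix and basement membrane genes 14 rose and 1 fell (15 and 4 adjusted over the list alone), with Lamb2 at 5.51 ± 0.55 and Col4a1 at 3.09 ± 0.45. Of 21 lymphatic genes 7 rose (9 up and 1 down adjusted over the list alone), among them Sox18 (6.82 ± 0.72) and Gata2 (5.38 ± 0.60), which blood endothelium also expresses, and Flt4. Prox1, the transcription factor gene that sets lymphatic identity, did not pass the test and stood lower in TAV, at 14.1 ± 26.3 against 54.4 ± 20.5 CPM (−2.29 ± 0.82, adjusted p = 0.102, edgeR). TAV 5 held 59.3 CPM of it and the other TAV libraries at most 4.25 CPM. Without TAV 5, Prox1 in TAV passed as lower (−4.46, adjusted p = 0.000484). Olig2, a marker of oligodendrocyte progenitors, also stood lower in TAV, at means of 2.79 against 92.6 CPM (scaled over all genes). Which cells carried Prox1 in bulk tumor cannot be told from these libraries, so its level there is no measure of lymphatic cells. Of 22 genes of tip cells and sprouting endothelium 7 rose (8 up and 1 down adjusted over the list alone). Camera's adjusted p was 1.52e-05 with the preset correlation, and the call was lost at adjusted p = 0.155 with an estimated correlation.

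The oligodendrocyte, progenitor, cell cycle, T and NK cell and neuronal lists were lower in TAV in camera. With the preset correlation their adjusted p was 6.25e-05, 8.88e-08, 1.62e-07, 4.51e-06 and 0.00103 in that order. These calls were lost at adjusted p = 0.0704, 0.137, 0.14, 0.14 and 0.155 with an estimated correlation. Over 21 settings the members lower adjusted over the list alone numbered 0 to 13, 0 to 15, 0 to 16, 0 to 9 and 0 to 7 in the same order. Of 16 oligodendrocyte genes 5 fell and 1 rose (9 and 1 adjusted over the list alone): the myelin enzyme gene Cnp fell (−2.73 ± 0.60), as did Ugt8a (−3.24 ± 0.77), while Mal rose (2.57 ± 0.42). Of 18 oligodendrocyte progenitor genes 8 fell (14 adjusted over the list alone), including Cacng4 (−3.43 ± 0.65), and of 24 cell cycle genes 3 fell (12 adjusted over the list alone), including cyclin gene Ccna2 (−3.17 ± 0.71). Of 16 T and NK cell genes 2 fell (9 adjusted over the list alone), and of 16 neuronal genes 2 fell (5 adjusted over the list alone), among them Syn1 (−4.37 ± 1.02). Outside the lists, the largest rises with reads in both groups included Bcam (8.18 ± 0.73) and Cavin2, a caveolar coat gene (7.60 ± 0.81), and the largest falls Timd4 (−6.36 ± 1.47), Ly6i (−5.70 ± 1.14) and Lrrtm3 (−5.59 ± 1.12). Of the named genes with 1 to 3 counts in a group, whether in a list or not, Tbx1 gave a ratio of pooled counts of 545 (97.4 to 21600) and Scgb3a1 one of 426 (76.1 to 16900).

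In edgeR's quasi-likelihood test 975 of 14846 genes differed between TAV and bulk tumor, 703 higher and 272 lower, and the CPM values of 1350 genes did not overlap between the groups (9.09%, against 0.794% by chance). The balance of higher and lower genes depended on the tool, with 1023 and 1000 in DESeq2 and 1844 and 1648 in voomWithQualityWeights. Camera called 17 of the 31 lists with the preset correlation, with adjusted p = 2.19e-43 for the pan-endothelial, 1.95e-41 for the blood-brain barrier, 7.83e-16 for the arterial, 1.74e-12 for the mural, 1.39e-08 for the matrix, 3.45e-08 for the VEGF and 5.35e-06 for the lymphatic list. These 7 kept their call with an estimated correlation, at adjusted p between 0.00024 and 0.0112, the arterial, mural and matrix lists in 19 of 21 settings and the others in 20; the calls of the other lists were lost. With day 80 only, where TAV had 1 library that is assumed to vary like the others, 42 genes were called, 48 of the 55 called genes of the text lost their call, and so did each of the 7 lists with an estimated correlation. Without bulk tumor 5 the test called 647 genes, and the count of lower genes was 117, against 127 without bulk tumor 4, 170 without TAV 3, 150 without TAV 4, 424 without bulk tumor 1 and 470 without TAV 5.

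**Figure D1:**
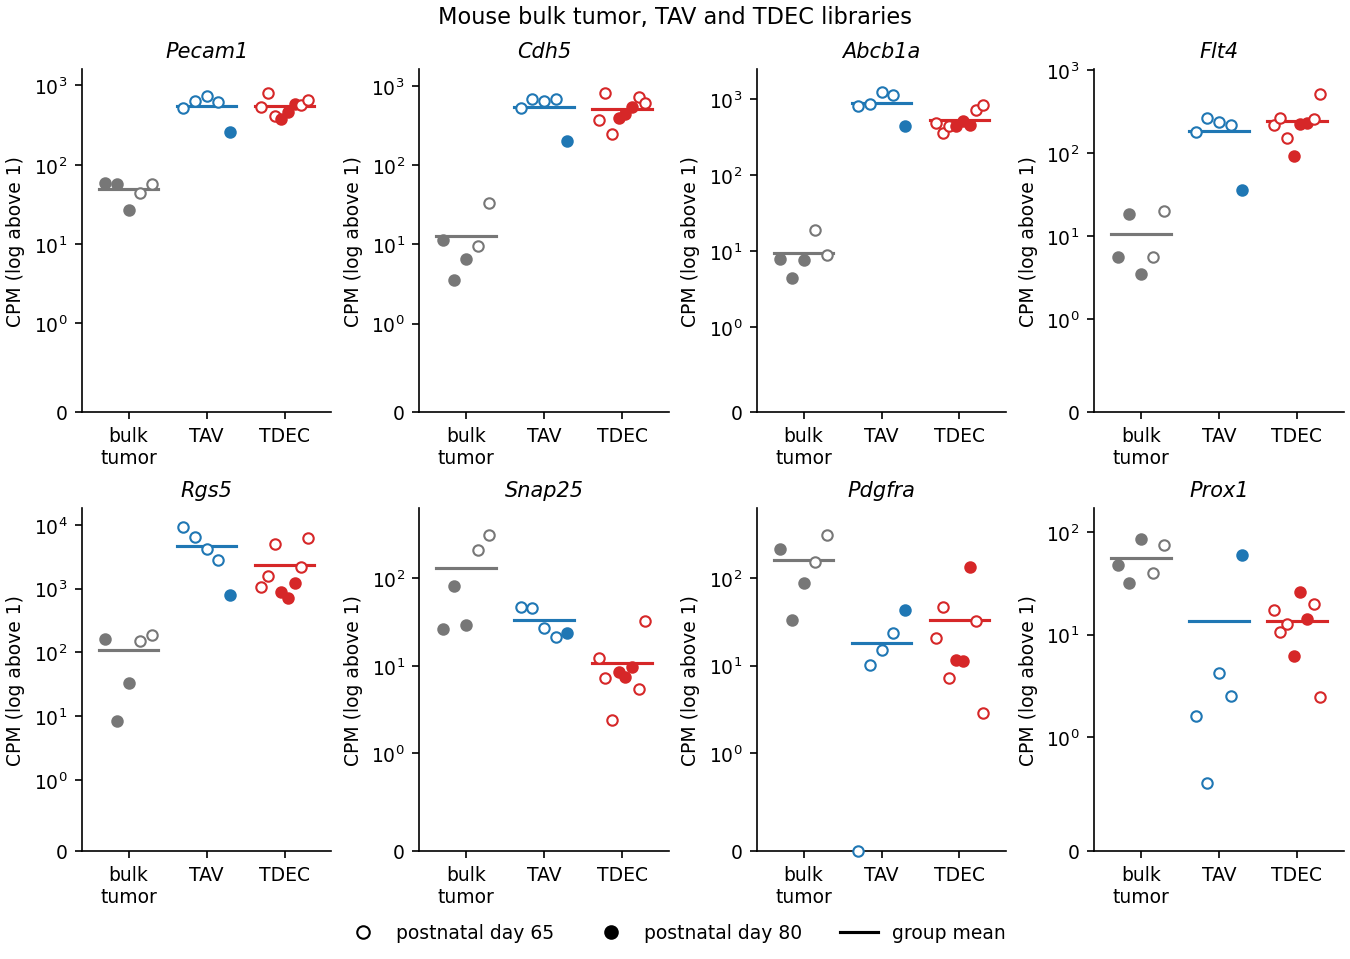
CPM of 8 genes (vertical axes, logarithmic above 1 CPM and linear below) in each bulk tumor, TAV and TDEC library; open points are postnatal day 65, filled points day 80, and bars are group means. Cdh5 reached at most 33.3 CPM in bulk tumor and was at least 202 CPM in each TAV and 245 CPM in each TDEC library, while Prox1 was at 32.3 CPM or more in each bulk tumor library and had means of 13.6 CPM in TAV, where TAV 5 alone was above 4.25 CPM, and 13.7 CPM in TDEC.

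TDEC libraries were compared with the same bulk tumor libraries. Endothelial genes again stood far above the tumor: of 25 pan-endothelial genes 24 rose (25 adjusted over the list alone), with Cdh5 at 519 ± 195 against 12.5 ± 11.1 CPM (5.37 ± 0.49), and all 24 blood-brain barrier genes rose (24 adjusted over the list alone), with Abcb1a at 539 ± 179 against 9.38 ± 5.44 CPM (5.77 ± 0.40), the Wnt-induced gene Apcdd1 (4.59 ± 0.48) and the amino acid transporter gene Slc38a5 (7.02 ± 1.05). Of 18 Wnt and Notch target genes 12 rose (12 adjusted over the list alone), including Lef1 (4.08 ± 0.43). Of 20 arterial genes 12 rose (17 adjusted over the list alone), among them Notch4 (6.35 ± 0.60), Dll4 (6.36 ± 0.89) and Bmx, which was at least 89.1-fold higher. Of 17 genes of venous and inflamed endothelium 8 rose (8 adjusted over the list alone).

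Matrix and sprouting genes rose in TDEC. Of 24 matrix and basement membrane genes 17 rose (18 up and 1 down adjusted over the list alone), among them the collagen IV gene Col4a1 at 727 ± 463 against 33.5 ± 14.4 CPM (4.36 ± 0.46) and the nidogen gene Nid1 (3.98 ± 0.43), and of 22 tip cell and sprouting genes 12 rose (17 adjusted over the list alone). Col4a1 and Nid1 are members of both lists. Of 18 genes of the endothelial-to-mesenchymal transition 5 rose (6 up and 1 down adjusted over the list alone), led by Fn1 (3.10 ± 0.37), Tgfbr2 (1.43 ± 0.29) and Itgb1 (1.25 ± 0.25), which resting endothelium also expresses. Mural cell genes rose beside these lists, 12 of 17 (14 adjusted over the list alone), with Rgs5 at 2390.0 ± 2160 against 105 ± 79.5 CPM (3.97 ± 0.68) and Pdgfrb, the pericyte receptor gene, at 4.47 ± 0.77. Of 21 lymphatic genes 7 rose (8 up and 1 down adjusted over the list alone), Sox18 (6.84 ± 0.68) and Flt4 (4.30 ± 0.55) among them, while Prox1 stood at 13.5 ± 7.18 against 54.4 ± 20.5 CPM (−1.78 ± 0.68, adjusted p = 0.149, edgeR; passing as lower in 3 settings, at −2.21 with voomWithQualityWeights) and Pdpn at 20.2 ± 33.2 against 5.53 ± 6.34 CPM (1.79 ± 1.24, adjusted p = 0.499, edgeR).

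Genes of neurons and oligodendrocytes were lower in TDEC. Of 16 neuronal genes 5 fell (6 adjusted over the list alone), including the synaptic genes Snap25 (−3.48 ± 0.53) and Camk2a (−2.46 ± 0.51). The list had adjusted p = 1.36e-06 with the preset and adjusted p = 0.0386 with an estimated correlation. Of 16 oligodendrocyte genes 3 fell and 1 rose (5 and 1 adjusted over the list alone), including Ermn (−2.81 ± 0.61) and, higher, Mal. This list had adjusted p = 5.74e-05 with the preset and adjusted p = 0.0454 with an estimated correlation. Of 16 T and NK cell genes 2 fell (8 adjusted over the list alone), and of 13 mitochondrially encoded genes 2 fell (6 adjusted over the list alone). They had adjusted p = 1.46e-07 and 0.00114 with the preset correlation, lost at adjusted p = 0.0678 and 0.361 with an estimated correlation. Over the settings the members lower adjusted over the list alone numbered 0 to 10 for neurons and 0 to 9 for oligodendrocytes and for T and NK cells, the last 0 without bulk tumor 4. Among the largest changes outside the lists were Igsf5, at least 128-fold higher, Wfdc1, with a ratio of pooled counts of 356 (98.3 to 2940), and falls of Celf4 (−3.08 ± 0.52) and Rasgrp1 (−2.97 ± 0.58).

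The test called 928 of 14846 genes between TDEC and bulk tumor, 789 higher and 139 lower, and 734 genes had no overlap of CPM values (4.94%, against 0.155% by chance). DESeq2 called 1116 higher and 444 lower, and voomWithQualityWeights 1215 and 897. Camera called 23 of 31 lists with the preset correlation, with adjusted p = 4.53e-53 for pan-endothelial, 3.2e-48 for blood-brain barrier, 3.41e-20 for matrix, 1.01e-18 for arterial, 9.66e-14 for tip cell, 3.82e-13 for mural, 2.84e-10 for Wnt and Notch, 8.94e-08 for lymphatic, 6.09e-07 for venous and 0.000451 for transition genes. Of the 23, 13 kept their call with an estimated correlation; the transition list, at adjusted p = 0.0272 with an estimated correlation, kept it in 22 of 24 settings, the neuronal list in 16 and the oligodendrocyte list in 13. With day 80 only 166 genes were called and 24 of the 51 called genes of the text lost their call, and the 139 lower genes became 51 without bulk tumor 4 and 47 without bulk tumor 5.

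**Figure D2:**
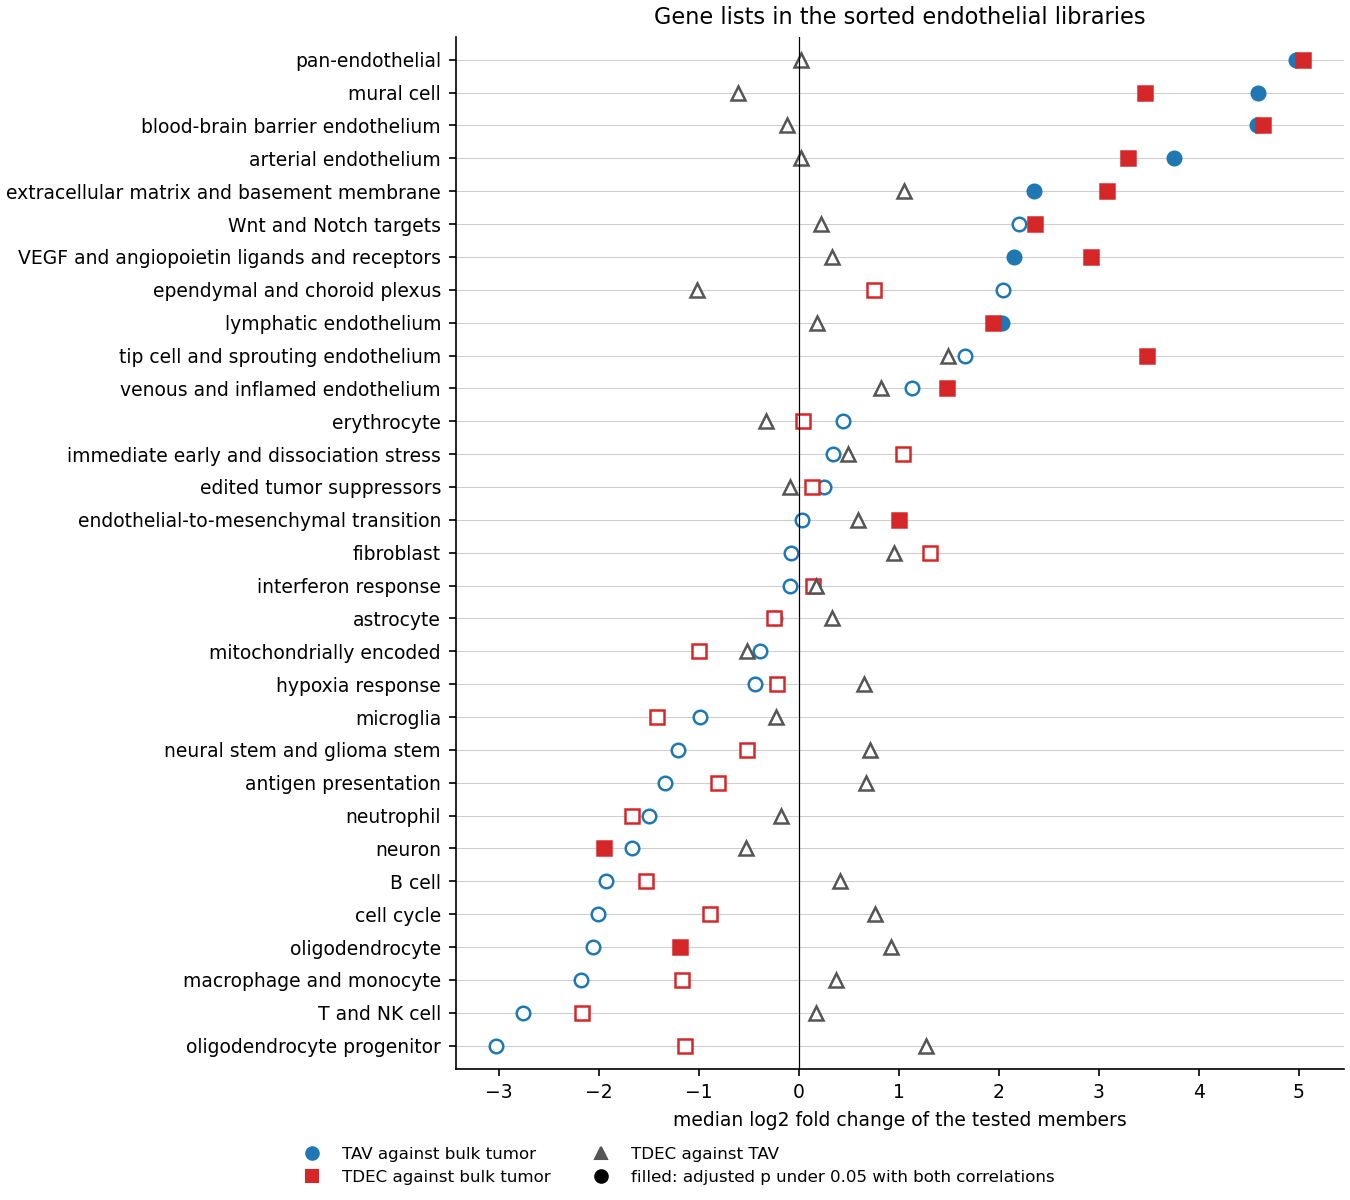
Median log2 fold change (horizontal axis) of the tested members of each fixed gene list (vertical axis) in TAV against bulk tumor (circles), TDEC against bulk tumor (squares) and TDEC against TAV (triangles); filled symbols had an adjusted p under 0.05 in camera with both the preset and the estimated correlation. The pan-endothelial and blood-brain barrier lists lay at medians of 4.98 and 4.58 in TAV and 5.05 and 4.64 in TDEC, and no list was filled in TDEC against TAV.

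TDEC and TAV were then set against each other, the relation the series' design text names. No gene passed the test over all genes, which called 35.0% of simulated 4-fold changes. Cdh5 stood at 519 ± 195 in TDEC and 575 ± 214 CPM in TAV (0.13 ± 0.39), and 0 of 25 pan-endothelial genes differed adjusted over the list alone. Pecam1, a sort marker, stood at 547 ± 137 and 582 ± 194 CPM (0.02 ± 0.29) and is no finding. Means of other endothelial genes lay further apart (scaled over all genes). Itm2a was at 448 CPM in TDEC and 867 CPM in TAV, Abcb1a at 536 and 901 CPM and Tek at 210 and 373 CPM. Cldn5 went the other way, at 340 and 182 CPM. As a group, matrix and sprouting genes were higher in TDEC, in 13 of 24 and 12 of 22 members adjusted over the list alone and 0 over all genes. Camera's adjusted p was 7.24e-07 and 1.9e-06 with the preset correlation, and the calls were lost at adjusted p = 0.0949 and 0.427 with an estimated correlation. The passing members fell to 0 in some of the 24 settings for both lists. Col18a1, the gene of a basement membrane collagen, stood at 76.5 ± 54.4 against 11.7 ± 9.91 CPM (2.97 ± 0.67), Lama4 at 343 ± 139 against 145 ± 54.5 CPM (1.41 ± 0.41) and Col4a1 at 727 ± 463 against 313 ± 106 CPM (1.27 ± 0.39). Other lists were called with the preset correlation only: fibroblast genes (2 of 16 adjusted over the list alone, Col1a1 at 3.44 ± 0.83), oligodendrocyte progenitor genes (2 of 18, Sox10 at 3.19 ± 0.79), transition genes (4 up and 1 down of 18) and cell cycle genes (0 of 24) were higher, and mural genes (0 of 17, Atp13a5 at −1.59 ± 0.53) lower. With the preset correlation their adjusted p was 0.00129, 0.00129, 0.0385, 0.00192 and 0.0456, in that order, and the calls were lost at adjusted p = 0.427, 0.81, 0.427, 0.81 and 0.81 with an estimated correlation. With the preset correlation the mural list was called in 15 of 24 settings, the transition list in 16 and the fibroblast list in 22. Camera's adjusted p for the fibroblast list was 0.0623 without TAV 5 and 0.076 without TAV 5 and TDEC 5 together. Without TAV 5, 8 transition members passed as higher and 1 as lower adjusted over the list alone, 2 cell cycle members as higher and 4 mural members as lower. Each of these genes had an adjusted p of 0.402 or more in edgeR's test. DESeq2 called Col18a1 (adjusted p = 0.00105), Col1a1 (0.00051) and Sox10 (0.0018), and voomWithQualityWeights Col18a1 (0.00422), Lama4 (0.0284), Col4a1 (0.0206), Col1a1 (0.0318) and Atp13a5 (0.00244).

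EdgeR's quasi-likelihood test called 0 genes between TDEC and TAV, with 1416 at an unadjusted p under 0.05 where chance gives 742, a lowest adjusted p of 0.188 and 56 genes without overlap (0.377%, against 0.155% by chance). DESeq2 called 155 genes, 125 higher and 30 lower, and voomWithQualityWeights 501, 140 higher and 361 lower, so the tools differed in the direction of most calls. For pan-endothelial genes camera's adjusted p was 0.668 with the preset correlation. With day 80 only, where TAV is the single library TAV 5, matrix genes had adjusted p = 0.158 with the preset correlation, and progenitor, mural and cell cycle genes turned direction (adjusted p = 0.832, 0.246 and 0.272). The median, mean and test differed in sign for 3 lists here, 1 in TAV and 2 in TDEC against bulk tumor, none of them called.

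The harvest at 2 ages allowed libraries of day 80 to be compared with those of day 65 within TDEC and within bulk tumor. Handling or batches that went with the day cannot be told apart from age here. In TDEC, mural genes were lower at day 80: 0 of 17 had a positive log2 fold change and 3 passed adjusted over the list alone. The list had adjusted p = 9.13e-06 with the preset correlation, lost at adjusted p = 0.126 with an estimated correlation. Without TDEC 5, and also without TDEC 2, 3, 4 or 8, 0 members passed. Its member Abcc9, a pericyte potassium channel subunit gene, stood at 85.0 ± 30.1 against 320 ± 140 CPM (−1.92 ± 0.52). All 20 interferon response genes had a positive log2 fold change, Mx1 at 2.25 ± 0.77 and Ifit2 at 1.55 ± 0.56, with 0 passing adjusted over the list alone. The list had adjusted p = 3.47e-05 with the preset correlation, lost at adjusted p = 0.539 with an estimated correlation. Without TDEC 5, 4 interferon and 3 B cell members passed. Jchain, an antibody chain gene of the B cell list, stood at 144 ± 128 against 12.1 ± 11.1 CPM (3.54 ± 0.97), and it was the 1 member of that list to pass adjusted over the list alone. The blood-brain barrier list was lower, with 0 members passing and Slc7a5 at −1.28 ± 0.50. The B cell and barrier lists each had adjusted p = 0.00357 with the preset correlation, lost at adjusted p = 0.531 with an estimated correlation.

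In bulk tumor, mitochondrially encoded genes were lower at day 80, 9 of 13 adjusted over the list alone (5 to 13 over the settings), with mt-Nd1 at 3155 ± 388 against 15950 ± 298 CPM (−2.34 ± 0.65). The list had adjusted p = 1.03e-13 with the preset correlation, lost at adjusted p = 0.154 with an estimated correlation. Immediate early genes, which tissue dissociation also induces, were higher, 7 of 20 adjusted over the list alone (1 to 7 over the settings, 1 without bulk tumor 4), with Fosb at 448 ± 514 against 10.3 ± 5.3 CPM (5.44 ± 1.01). This list had adjusted p = 5.73e-09 with the preset correlation, lost at adjusted p = 0.264 with an estimated correlation. Neuronal genes were lower, with 1 of 16 positive and 0 passing adjusted over the list alone (Snap25 at 45.3 ± 30.9 against 251 ± 66.2 CPM), and so were hemoglobin and other erythrocyte genes, 4 of 5 adjusted over the list alone (0 without bulk tumor 4; Hba-a2 at −5.26 ± 1.09) and 7 of the blood-brain barrier genes (0 to 7 over the settings). The neuronal, erythrocyte and barrier lists had adjusted p = 1.61e-08, 5.94e-07 and 2.38e-05 with the preset correlation, lost at adjusted p = 0.105, 0.137 and 0.264 with an estimated correlation. The B cell list was higher, with 2 members passing (0 without bulk tumor 2 or 5; Jchain at 5.23 ± 1.53). It had adjusted p = 0.000196 with the preset correlation, lost at adjusted p = 0.281 with an estimated correlation. None of these genes passed over all genes, but without bulk tumor 1 Fosb did in bulk tumor by age (adjusted p = 0.0388). DESeq2 called Fosb (adjusted p = 1.08e-07), Hba-a2 (8.03e-05), Jchain (0.00289) and mt-Nd1 (0.0493). The difference of the age effect between TDEC and bulk tumor was negative for the immediate early list, with 7 members adjusted over the list alone (2 to 11 over the settings; Fosb at −6.83 ± 1.19), and positive for the erythrocyte list, with 4 (0 without bulk tumor 4). These lists had adjusted p = 2.11e-11 and 3.12e-07 with the preset correlation, lost at adjusted p = 0.278 and 0.213 with an estimated correlation.

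EdgeR's quasi-likelihood test called 0 genes by age in TDEC (584 at an unadjusted p under 0.05, where chance gives 742), against 6 with DESeq2, 0 with voomWithQualityWeights and 2 without TDEC 5. In bulk tumor it called 1, Gm3608, a predicted pseudogene on chromosome 1 (105455971 to 105458829) that was named after its values were seen; it stood at 104 ± 57.6 CPM at day 80 with no read at day 65, at least 307-fold higher (adjusted p = 0.00897). It was also the 1 gene whose age effect differed between TDEC and bulk tumor (adjusted p = 0.0175, edgeR), with 31.5 ± 19.9 CPM at day 80 and 38.8 ± 23.8 CPM at day 65 in TDEC. Its value is uncertain, since estimated counts can split reads between a pseudogene and its near copies. The call ended without bulk tumor 4 (0 genes) and without bulk tumor 5 (0 genes), the only day 65 libraries, and with voomWithQualityWeights; without bulk tumor 1 and without bulk tumor 3 there were 2 and 3 genes by age, and 2 in each case for the difference. Non-overlapping genes were no more frequent than by chance in TDEC (3.32% against 3.57%) and were 21.2% against 20.0% in bulk tumor.

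Some lists called by age lost their call without 1 library. Without TDEC 4 the interferon list had adjusted p = 0.106, the B cell list 0.579 and the barrier list 0.283 with the preset correlation, the highest over 16, 15 and 16 settings. In bulk tumor by age the B cell list had adjusted p = 0.156 without bulk tumor 5, the highest over 13 settings. The median, mean and test differed in sign for 2 lists in TDEC by age, 7 in bulk tumor by age and 8 in the difference, none of them called.

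Mouse TDLEC, the fraction labelled lymphatic, was compared with TDBEC, the fraction labelled blood endothelial. The lymphatic genes that define such cells were low in both. Prox1 stood at 6.87 ± 7.04 CPM in TDLEC and 14.6 ± 10.6 CPM in TDBEC (−1.09 ± 0.83), Pdpn, a sort marker, at 9.49 ± 8.74 and 2.38 ± 2.37 CPM (2.00 ± 1.14) and Flt4, also a sort marker, at 44.2 ± 27.9 and 32.9 ± 19.9 CPM (0.43 ± 0.57). Olig2 had means of 25.4 CPM in TDLEC and 117 CPM in TDBEC (scaled over all genes), and which cells carried Prox1 in either fraction was not tested. Of 16 lymphatic genes 1 passed adjusted over the list alone: Stab1, a scavenger receptor gene that macrophages also express, at 61.8 ± 7.59 against 23.9 ± 11.4 CPM (1.37 ± 0.31). The list had adjusted p = 0.0945 with the preset and adjusted p = 0.381 with an estimated correlation. Without TDLEC 2, 3 or 5 the lymphatic list in TDLEC was called with the preset correlation (adjusted p = 0.0471, 0.0473 and 0.0312), and over 16 settings its adjusted p was 0.343 or more with an estimated correlation. Pecam1 was at 193 ± 110 and 194 ± 131 CPM.

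Some lists differed between these fractions with the preset correlation only. All 20 interferon response genes had a positive log2 fold change in TDLEC, and 6 passed adjusted over the list alone, with Isg15 at 219 ± 87.4 against 92.0 ± 30.2 CPM (1.25 ± 0.36) and Ifitm3 at 1571 ± 573 against 635 ± 207 CPM (1.31 ± 0.38). This list had adjusted p = 5.23e-10 with the preset correlation, lost at adjusted p = 0.339 with an estimated correlation. Microglia genes went the same way, with 17 of 18 positive, 0 passing adjusted over the list alone (12 without TDBEC 1) and median sums of 10300 CPM in TDLEC and 4960 CPM in TDBEC. They had adjusted p = 1.38e-05 with the preset correlation, lost at adjusted p = 0.381 with an estimated correlation. The microglia list includes the endothelial gene Sparc, so its sums are not of microglia RNA alone. Mitochondrially encoded genes were positive in 13 of 13 members with 0 passing adjusted over the list alone, and venous genes in 16 of 16 with 0 passing (Vcam1 at 1.86 ± 0.55). They had adjusted p = 7.3e-10 and 1.38e-05 with the preset correlation, lost at adjusted p = 0.339 and 0.16 with an estimated correlation. Mural genes were higher, 5 of 17 adjusted over the list alone (Tagln at 4.09 ± 0.99 and Higd1b at 2.72 ± 0.67), and transition genes 4 of 18 (Vim at 0.92 ± 0.24). They had adjusted p = 1.06e-05 and 4.81e-05 with the preset correlation, lost at adjusted p = 0.339 and 0.0569 with an estimated correlation. Oligodendrocyte genes were lower, 2 of 18 adjusted over the list alone, with the myelin gene Mag at 43.7 ± 24.7 against 264 ± 254 CPM (−2.59 ± 0.62). The list had adjusted p = 2.49e-07 with the preset correlation, lost at adjusted p = 0.339 with an estimated correlation. Which members passed turned on single libraries: over the settings 0 to 9 interferon, 0 to 13 mitochondrial (13 without TDBEC 4 and 11 without TDLEC 4), 0 to 4 venous, 0 to 10 mural, 0 to 4 transition and 0 to 8 oligodendrocyte members did. Both fractions held myelin and antibody RNA: Mbp averaged 11240 CPM in TDLEC and 35950 CPM in TDBEC, and Igkc was at 78410 and 84760 CPM in 2 of the TDBEC libraries and at most 8320 CPM in TDLEC.

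**Figure D3:**
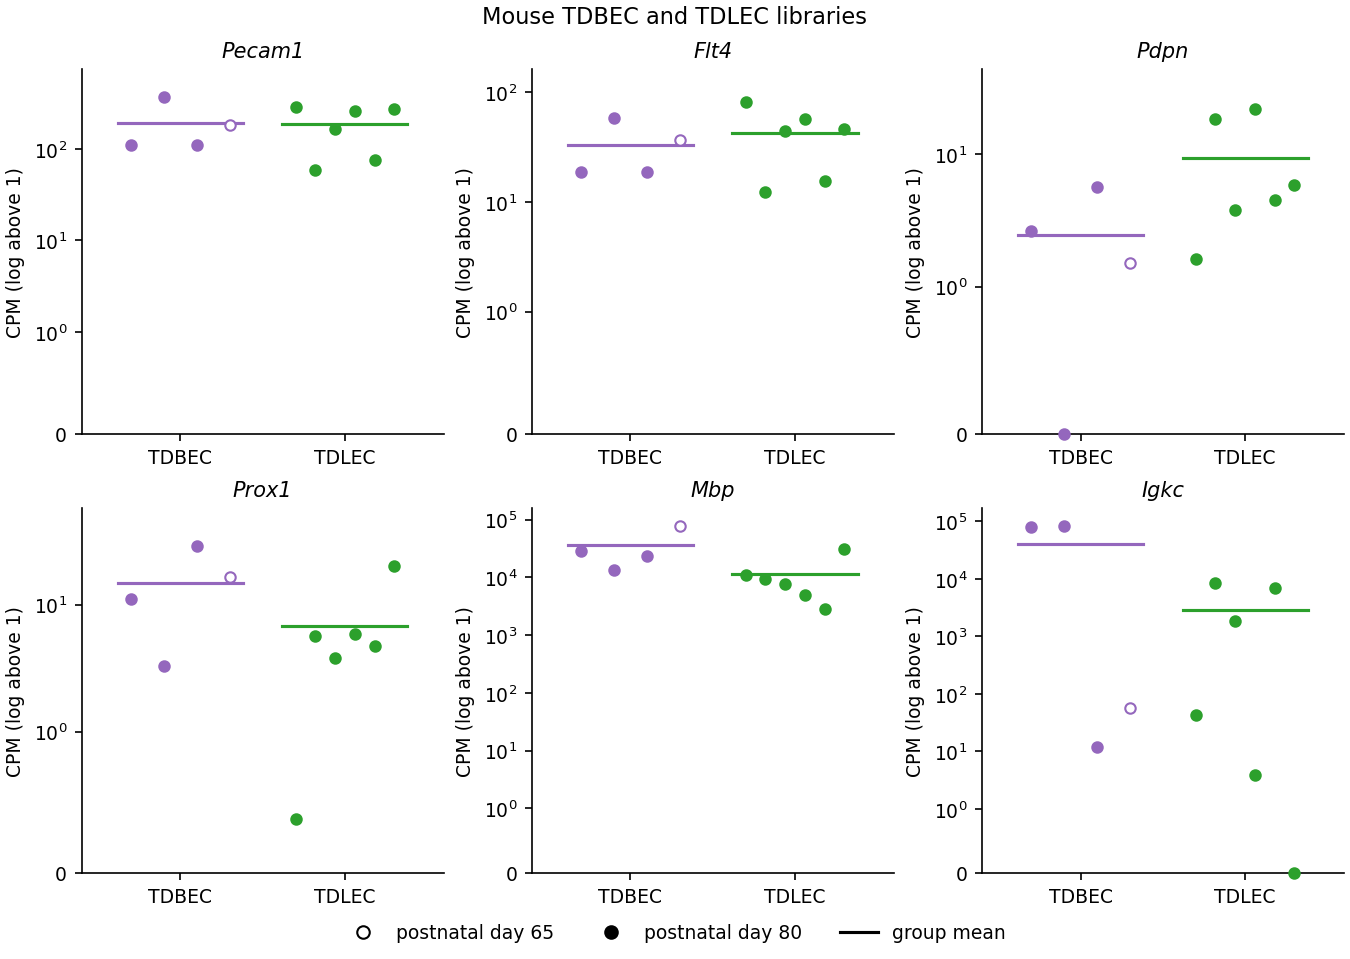
CPM of 6 genes (vertical axes, logarithmic above 1 CPM and linear below) in each mouse TDBEC and TDLEC library; open points are postnatal day 65, filled points day 80, and bars are group means. Prox1 reached 28.8 CPM in TDBEC and 20.3 CPM in TDLEC, and Mbp was at least 2849 CPM in each library.

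EdgeR's quasi-likelihood test called 0 of 14762 genes between TDLEC and TDBEC, with 1169 at an unadjusted p under 0.05 where chance gives 738, a lowest adjusted p of 0.135, and 303 genes without overlap (2.05%, against 0.952% by chance). DESeq2 called 175 genes and voomWithQualityWeights 0; without TDBEC 4, the only library of day 65, edgeR called 1. Camera called 19 lists with the preset correlation and 0 with an estimated correlation.

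In the human xenografts, no transcript passed the test between TDLEC and TDBEC. EdgeR's quasi-likelihood test called 0 of 18278 transcripts, with 1082 at an unadjusted p under 0.05 where chance gives 914, and a lowest adjusted p of 0.0802. The biological coefficient of variation was 2.05, against 0.745 in the mouse TDLEC and TDBEC libraries, which were tested per gene. DESeq2 called 1344 transcripts, 119 higher and 1225 lower, and voomWithQualityWeights 107, 102 higher and 5 lower, so the tools pointed opposite ways. The count was 50 without TDLEC 1 and 164 without TDLEC 2, fits with 1 TDLEC library in which the spread comes from TDBEC alone. Transcripts without overlap were no more frequent than by chance (9.15%, against 9.52%), and with 2 TDLEC libraries the test called 2.0% of simulated 16-fold changes.

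The single-cell libraries show which cells the tumor and the CD31-enriched preparation held. In the bulk tumor library, with 6678 cells after filtering, T or NK-like cells made up 42.6% (41.4% to 43.8%), microglia-like cells 15.3% (14.4% to 16.2%), astrocyte-like cells 12.1%, oligodendrocyte progenitor-like cells 8.21% and endothelial-like cells 1.33% (89 cells; 1.07% to 1.64%). In the CD31-enriched library, with 2667 cells, endothelial-like cells made up 93.0% (2480 cells; 92.0% to 93.9%), mural-like cells 3.34% and microglia-like cells 1.09%, a makeup that the enrichment itself sets. No macrophage, neuron or choroid plexus-like cell was seen there, which allows a share of each of up to 0.112%, taking 3 cells of 2667 as the limit of a count of 0 (0.138% by the exact 95% interval). The endothelial-like share was 1.33% to 1.38% and 93.0% to 93.7% over 6 settings, while the T or NK-like share of the bulk tumor ranged from 42.0% to 49.1%. In the bulk tumor library 8.04% of cells lay in clusters that stayed unnamed (0.389% to 8.76% over 6 settings). The erythroid-like cluster had 3 endothelial markers among its top 10 genes and was not compared between libraries. Over all cells of the files, before filtering, median depth was 2259.5 UMIs in the bulk tumor and 1452 in the enriched library.

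**Figure D4:**
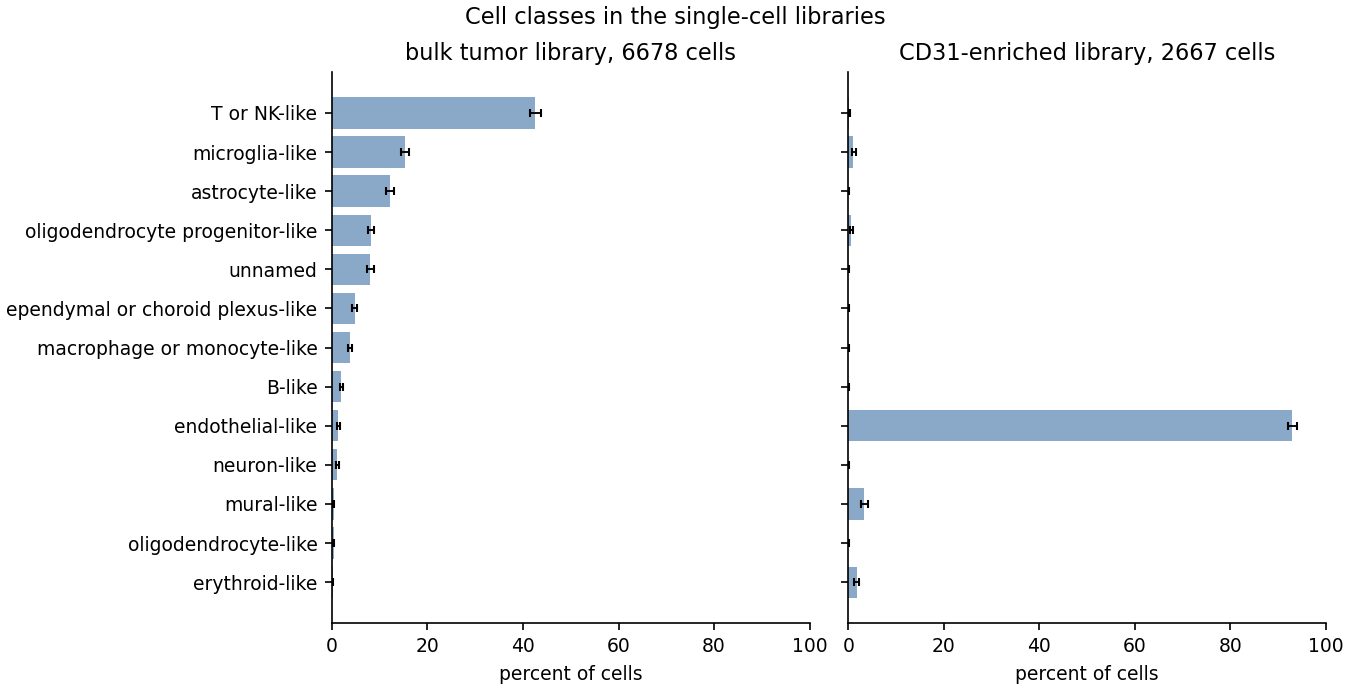
Percent of cells (horizontal axes) per cell class (vertical axis) in the bulk tumor library and the CD31-enriched library, 1 library each; bars are shares and lines are exact 95% intervals that cover counting error only. T or NK-like cells were 42.6% of the bulk tumor library and endothelial-like cells 93.0% of the enriched one.

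Endothelial-like cells of the 2 libraries differed in immune genes. Of the 89 in the bulk tumor library 77 lay in cluster 19, while those of the enriched library lay in clusters 22 (1299 cells), 23 (969) and 24 (210), so the values set different clusters side by side, with no test. The antigen presentation gene Cd74 stood at 5620 CPM in bulk tumor and 0.661 CPM in enriched endothelial-like cells, a ratio of 8500 (3640 to 26200), H2-Ab1 at 1870 and 4.36 CPM, and the interferon-induced chemokine genes Cxcl9 at 713 and 1.45 CPM and Cxcl10 at 2170 and 6.21 CPM. Ccl5, a chemokine gene, had the highest ratio, at 2200 and 0.132 CPM (16600; 2970 to 658000). The T and NK cell list summed to 4860 CPM in the endothelial-like cells of the bulk tumor, against 18700 CPM in T or NK-like cells. Ccl5 alone stood at 2200 CPM in those endothelial-like cells, and whether this RNA came from T or NK cells was not tested. The microglia list, which includes the endothelial gene Sparc, summed to 4270 CPM there, to 3180 CPM in enriched endothelial-like cells and to 41500 CPM in microglia-like cells of the bulk tumor. Of 18 interferon response genes 0 were higher in the enriched library (median log2 ratio of enriched over bulk tumor −2.31, below all 10000 random lists), and of 12 antigen presentation genes 0 were (−3.43). Blood-brain barrier genes went the other way, 22 of 24 higher in the enriched library (1.12, percentile 100.0), as did 15 of 17 arterial genes (1.32, percentile 100.0), while pan-endothelial genes had a median of 0.23 (percentile 85.6). Mitochondrially encoded genes were also higher there, 12 of 13 (0.92, percentile 99.8), and the median mitochondrial share per cell over all cells was 7.35% in the enriched and 3.55% in the bulk tumor library. Of the genes with no UMI in the 89 bulk tumor cells, Hba-a1 (at least 10.4-fold) and Akap2 (at least 10.2-fold) had the most in the enriched library. Mural-like and microglia-like cells of the bulk tumor library also held more interferon list RNA than those of the enriched one, at 18300 against 3040 CPM and 7360 against 3510 CPM. The microglia-like cells lay in clusters 2 (734 cells) and 15 (288) in the bulk tumor and in cluster 2 alone in the enriched library, and within cluster 2 the values were 7490 against 3510 CPM. For the summed antigen presentation list the ratio of bulk tumor over enriched was 5.75 (5.61 to 5.89) in endothelial-like cells. It was 6.48 (6.04 to 6.96) in mural-like and 5.99 (5.27 to 6.84) in microglia-like cells, so this difference was not particular to endothelial-like cells.

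Prox1, Lyve1 and Pdpn were hardly seen in endothelial-like cells, and Flt4 was. Prox1 was seen in 0 of the 89 cells of the bulk tumor library, at a depth where a cell without a UMI need not lack it, and was not listed in the enriched library; Lyve1 was listed in neither. Pdpn was seen in 1 of 89 and 0 of 2480 cells, against 22.3% of astrocyte-like cells in the bulk tumor library. Flt4 was seen in 6.74% (2.51% to 14.1%) of endothelial-like cells in bulk tumor and 14.1% (12.7% to 15.5%) in the enriched library, at 38.1 and 55.7 CPM, against 0.196% of microglia-like cells in bulk tumor; after thinning to 500 UMIs the shares were 2.25% and 2.9%. Median depth was 1388 UMIs in endothelial-like cells of the bulk tumor, 1582.5 in those of the enriched library and 1262 in microglia-like cells of the bulk tumor.

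EGFP, a reporter listed only in the bulk tumor library, was among the genes used for clustering and leads a progenitor-like cluster. A UMI of it was seen in 6.54% of all cells, in 43.8% (39.6% to 48.1%) of oligodendrocyte progenitor-like cells at 7590 CPM, in 5.18% of astrocyte-like cells, in 2.15% (1.35% to 3.24%) of microglia-like cells and in 2.0% of T or NK-like cells. Of the 89 endothelial-like cells 4 had one, 4.49% (1.24% to 11.1%). This interval reaches that of the microglia-like cells, so a share above theirs was not detectable with 89 cells.

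**Figure D5:**
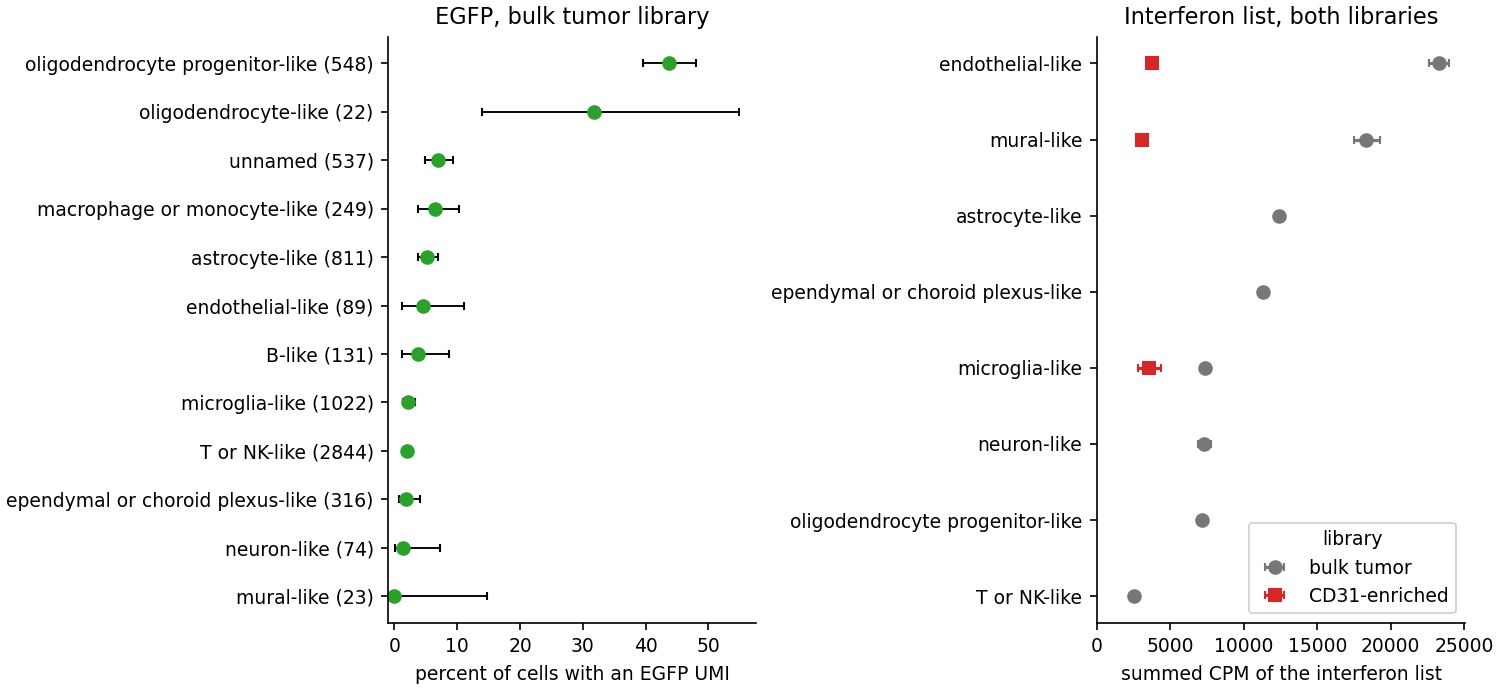
Left, percent of cells with an EGFP UMI (horizontal axis) per cell class of 20 or more cells in the bulk tumor library, with cell numbers in parentheses; right, summed CPM of the interferon response list (horizontal axis) per class in the bulk tumor (circles) and CD31-enriched (squares) libraries, with exact 95% intervals that cover counting error only. Progenitor-like cells had the highest EGFP share, 43.8%, and endothelial-like cells held 23300 CPM of the interferon list in the bulk tumor and 3740 CPM in the enriched library.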

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

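The tests of sequencing depth and of RNA of other cell types in TDLEC were chosen after the result was seen; the test of diluted lymphatic cells and the splits of the libraries were set before.

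Among 71 groups of 4 to 8 libraries, 13 held a library whose gap to the next was large for its group. The cut would flag about 1 in 20 groups of normally distributed values. CPM values and reads need not be normal, and the groups share libraries, so the 13 are no measure of an excess over chance. A group with reads in 1 library only, as for Lyve1 in TDBEC and in TDLEC, is flagged by construction. TAV 5, the only TAV library of day 80, stood apart in Igkc (0.071% of its reads, next 0.005%), in Prox1 (59.3 CPM, next 4.25 CPM) and, as the lowest, in Kdr (185.5 CPM, next 403.4 CPM). TDEC 5 held 109.6 CPM of Pdpn, from 59 reads, where the next TDEC library held 12.0 CPM, TDEC 8 held 513.4 CPM of Flt4 (next 265.5 CPM) and TDEC 2 held 20.2 CPM of Lyve1 (next 9.20 CPM). Bulk tumor 5 had the most Cdh5 (33.3 CPM, next 11.3 CPM) and Kdr (38.8 CPM, next 16.9 CPM), and bulk tumor 4 the most Lyve1 (16.1 CPM, next 3.9 CPM). TDLEC 2 had 69434466 reads (69.4 M), where the next had 12410009 (12.4 M), and was with TDBEC 2 the only library of its group with a read of Lyve1 (1.85 and 0.877 CPM). TDLEC 6 held 20.3 CPM of Prox1, next 5.91 CPM. The age effect of Gm3608 was lower in TDEC than in bulk tumor in a test of the difference itself; the fitted log2 value of −12.47 is not a measured size, since bulk tumor held no read of it at day 65.

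The TDLEC libraries held little RNA of lymphatic genes: their summed CPM was 5.74% to 17.4% of that of the pan-endothelial list, against 5.79% to 17% in TDBEC. Depth was too high to hide them, since a gene at 10 CPM would give 85.9 reads in the shallowest TDLEC library. If lymphatic cells were there but diluted by RNA of other cells, the ratio of lymphatic to pan-endothelial genes would still be higher in TDLEC. It was lower by a mean log2 difference of −0.33, with a two-sided exact permutation p = 0.438 over 210 splits, so a dilution cannot be excluded or shown with this spread. RNA of other cell types may have carried part of the signal. Oligodendrocyte and microglia genes summed to 0.854 to 12.2 times the pan-endothelial list in TDLEC, with 1 library under 1, and 2.65 to 16.4 times in TDBEC. The microglia list includes the endothelial gene Sparc and summed to 3180 CPM in endothelial-like cells of the CD31-enriched single-cell library. Part of these sums can thus come from endothelium. The lists also hold genes of unlike levels, so the ratio measures no share of other RNA. From it, dilution and a gate that took few lymphatic cells cannot be told apart.

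Other splits of the same libraries show how often such counts arise under other groupings. TAV against bulk tumor called 975 genes and the highest of the other splits 115, and TDEC against bulk tumor called 928 and the highest other 6. In both cases 1 of 100 splits (the real one) was as large. These were taken from 126 and 1287 possible splits, so chance is unlikely but not excluded. For TDEC against TAV (0 genes; highest other 7), mouse TDLEC against TDBEC (0; highest other 4) and TDEC at day 80 against day 65 (0; highest other 307) the real count was 0, so 100 of 100, 100 of 100 and 56 of 56 splits were as large by construction and the splits decide nothing about chance. The split with 307 genes is the highest of the TDEC splits by age, whose median was 0, and what that count follows was not examined.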

How the results depend on the processing

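Removal of Lars2, Gm20594 and Gm10800, removal of immunoglobulin genes, leaving out TAV 5 and TDEC 5 together and the doublet score limit of 0.25 were chosen after the data were seen; the other settings were planned. Over all settings, 3715 values of genes in the text kept direction and side of the threshold, 202 lost their call, 45 gained one and 23 changed sign; for gene lists the numbers were 1046, 31, 3 and 3, and 17 of 120 cell type shares moved beyond their interval. Gained calls were from DESeq2 or voomWithQualityWeights, apart from those of Prox1 in TAV (day 65 only, without TAV 5, and without TAV 5 and TDEC 5 together), Prox1 in TDEC (only the 2 cell types compared, adjusted p = 0.0169, and without TAV 5 and TDEC 5 together, 0.0118), Fosb without bulk tumor 1 and the lymphatic list in TDLEC. Each cause was not tested unless fewer libraries or genes in the setting show it. The 3 human settings that need gene names (removal of mitochondrial genes, the top 300 mouse genes and the estimated correlation in the cross-species test) were not run. TDEC 5 was the shallowest library, at 663449 reads.

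TAV against bulk tumor (975) gave 2023 genes with DESeq2, 3492 with voomWithQualityWeights and 42 with day 80 only, and 647 to 1246 without each library. TDEC against bulk tumor (928) gave 1560 with DESeq2, 2112 with voomWithQualityWeights and 166 with day 80 only, and 621 to 948 without each library. TDEC against TAV (0) gave 155 with DESeq2, 2 with no filter, 501 with voomWithQualityWeights and 3 with day 80 only, and 0 without each library. Fewer libraries enter the day 80 settings; the cause of the other changes was not tested. With DESeq2 size factors 681 genes were higher and 341 lower in TAV and 750 and 190 in TDEC.

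TDEC by age (0) gave 6 with DESeq2, 2 with no filter and 2 without TAV 5 and TDEC 5 together, and 0 to 2 without each library. Bulk tumor by age (1) gave 64 with DESeq2, 0 with voomWithQualityWeights, 2 with the transcript-length offset and 0 with only that cell type, and 0 to 3 without each library. The difference of age effects (1) gave 19 with DESeq2 and 0 with voomWithQualityWeights, and 0 to 2 without each library; DESeq2 size factors moved its median over all genes from −0.23 to −0.09 and that of the human comparison from −0.29 to −0.18. Mouse TDLEC against TDBEC (0) gave 175 with DESeq2 and 1 with day 80 only, and 0 to 1 without each library. The human comparison (0) gave 1344 with DESeq2, 76 with no filter and 107 with voomWithQualityWeights, and 0 to 164 without each library. The cause was not tested.

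With an estimated correlation the lists called fell from 17 to 7 for TAV and 23 to 13 for TDEC against bulk tumor, and to 0 from 9 for TDEC against TAV, 9 for TDEC by age, 10 for bulk tumor by age, 9 for the difference and 19 for mouse TDLEC. After thinning to 500 UMIs, Flt4 was seen in 2.25% and Pecam1 in 13.5% of endothelial-like cells of the bulk tumor (from 6.74% and 40.4%) and in 2.9% and 26.0% in the enriched library (from 14.1% and 63.1%), by construction.

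Among genes, changes of sign were confined to values that passed no test over all genes in the reported fit, though Prox1 in TAV against bulk tumor and Vtn in TDEC against TAV passed in other settings (adjusted p = 0.000102 and 0.0148 with voomWithQualityWeights). Prox1 in TAV was 0.12 with day 80 only. Nf1 in TAV was −0.049 with voomWithQualityWeights, −0.16 with day 65 only and −0.079 without TAV 5 and TDEC 5 together, and −0.24 (without TAV 5) to 0.37 without each library; in TDEC it was 0.053 with the length offset and −0.19 to 0.002 without each library. With day 65 only, Pdpn in TDEC was −0.25. Between TDEC and TAV, Pecam1 was −0.05 with voomWithQualityWeights, −0.089 with no age term, −0.13 with day 65 only and −0.14 without TAV 5 and TDEC 5 together, and −0.12 to 0.13 without each library, negative without TAV 5, TDEC 2 or TDEC 6; Prox1 was −0.10 with no age term and −2.05 with day 80 only, and Vtn 0.60 with day 80 only. The progenitor, mural and cell cycle lists turned there at adjusted p = 0.832, 0.246 and 0.272, against 0.00129, 0.0456 and 0.00192 in the reported fit. Pecam1 in mouse TDLEC was 0.25 with voomWithQualityWeights and −0.27 to 0.56 without each library, positive without TDBEC 2 or TDLEC 2, 3 or 5. The cause was not tested.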

Other observations

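The tests of free RNA, doublets, the whole library and carried-over EGFP were chosen after the results were seen.

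Immune RNA in the bulk tumor library reached beyond endothelial-like cells. Summed over the interferon response list, endothelial-like cells (cluster 19 in the main) held 23300 CPM (22600 to 24000), mural-like cells 18300 CPM, astrocyte-like cells 12400 CPM, choroid plexus-like cells 11300 CPM, neuron-like cells 7310 CPM and T or NK-like cells 2500 CPM. In endothelial-like cells, other genes with high ratios to the enriched library were Cd52, at 686 and 0.264 CPM, H2-Eb1, at 621 and 0.397 CPM, and Gbp8, at 686 and 0.661 CPM. VEGF and angiopoietin genes were higher in the enriched library in 12 of 14 cases (median log2 ratio 0.69, percentile 99.0 of random lists), and so were 14 of 19 immediate early genes (0.62, percentile 99.2), while sprouting genes were higher in 6 of 16 (−0.32, percentile 0.51).

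Antibody light chain RNA varied between libraries of 1 group. Igkc stood at 2247 to 32270 CPM in the bulk tumor libraries of day 80 and at 0.862 and 420 CPM in those of day 65, at 6518, 1.858 and 4435 CPM in TDEC 4, 5 and 6, the TDEC libraries of day 80, at 0.163 to 425.3 CPM in those of day 65, and at 677 CPM in TAV 5. Igkc differed by 6.32 ± 3.63 (log2) by age in bulk tumor with adjusted p = 0.86 in edgeR's quasi-likelihood test. TDLEC 4 held 13460 CPM of Ttr, a choroid plexus gene.

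For the interferon genes in endothelial-like cells of the bulk tumor library, free RNA is argued against, since the list was 4.05 times (3.92 to 4.17) as high in endothelial-like cells as in all other cells of the library. Doublets with microglia-like or T or NK-like cells are argued against as the whole source, since the RNA of the microglia and T and NK lists in these cells would bring 6.04% of the level seen. Doublets with cells of other classes were not tested. A difference of the whole library remains open: the ratio of bulk tumor over enriched was 6.03 (5.56 to 6.55) in mural-like and 2.1 (1.7 to 2.63) in microglia-like cells (2.13, 1.72 to 2.68, within cluster 2, the 1 such cluster that both libraries share), against 6.22 (6.03 to 6.43) in endothelial-like cells, so another tumor, preparation or batch may account for it. With 1 library of each kind no biological explanation was tested.

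Whether tumor cells contribute endothelial cells is a question that EGFP in endothelial-like cells could bear on, if EGFP marks electroporated cells. The share of endothelial-like cells with a UMI, 4.49% (1.24% to 11.1%), reached the share of microglia-like cells, 2.15% (1.35% to 3.24%). Shares alone cannot tell carried-over EGFP from other sources, since they ignore how many UMIs a cell holds. Among microglia-like cells 8 had 5 or more UMIs, with a maximum of 88, so these cells are no measure of carried-over EGFP alone. Of the 4 endothelial-like cells with EGFP 2 had 5 or more UMIs, with a maximum of 24. If these were doublets with progenitor-like cells, their EGFP would come with 13.7 UMIs of the progenitor list, where 1 was seen (0.0253 to 5.57), but 15.1% of 192 progenitor-like cells with 5 or more EGFP UMIs had as low a ratio, so doublets and expression cannot be told apart with 4 cells.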
